A study of Mus musculus with 2 samples.

How the data were processed

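Histone H3 lysine 9 acetylation (H3K9ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse midbrain dissected at embryonic day 12.5. Per the labels' protocols, the tissue came from B6NCrl embryos of mixed sex in 2 biological replicates, of which replicate 1 pooled 120 embryos and replicate 2 pooled 88. The deposited description of the pooled and replicated lists names 1 technical replicate of replicate 1 and 2 of replicate 2. Whether this adds to differences between the replicates' lists was not tested. Both samples form 1 group, so no comparison between conditions exists. The labels name the same strain source for both pools, and no test across samples was run with 2 samples.

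The deposited data are 4 lists of narrowPeak intervals on mm10, the UCSC name for mouse genome build GRCm38. Per the file headers, 1 list was called on replicate 1 alone and 1 on replicate 2 alone, each with 1 further file of its own, and 1 list came from the alignments of both replicates together with 2 further files. The replicated list was derived, per the file headers, from both replicates' lists and the pooled list. The rule that admits a peak to it is not given in the sources used here, nor are the aligner, the peak caller and their versions. The fold enrichment of each peak is the authors' own value, read from the signal column of the deposited files as a ratio of ChIP over control. Its reading as a ratio rests on the file format and on values from 1.21 upward. The authors' p-values and q-values were deposited as −log10 values, and the lowest −log10 p was 2.01 in replicate 1 and 2.03 in replicate 2. Fold enrichment was used to describe, rank or filter peaks within a list and for the rank correlation of the replicates. Its ranks were also compared between the replicates' lists by gene list, and no change between lists was called from them. The lists hold no read counts, so the depth of each sample is unknown, and no interval that needs depth is given. Binomial intervals are given over genes and cover only the sampling of genes.

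Positions were set against GENCODE M21 and the GRCm38.p6 sequence. No peak ran past a chromosome end. The 21 main chromosomes held 21938 protein-coding genes with 93513 transcription start sites (TSSs), and 132721 TSSs over the 55413 genes of all types. Peaks on unplaced or unlocalized scaffolds, 7 in the replicated list, 10 in the pooled list, 11 in replicate 1 and 7 in replicate 2, were left out of all location and gene results. Coordinates are 1-based on mm10.

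Overlaps were computed with bedtools 2.31.1 and required at least 1 shared base. Peaks were shuffled 20 times within their chromosomes outside assembly gaps with fixed seeds to give a reference. A peak within 1 kb of any TSS was assigned to promoters, remaining peaks to exons, then to introns, then to the space between genes. A protein-coding gene took the strongest peak and the widest domain within 1 kb of any of its TSSs, with peaks 1 kb or less apart joined into a domain. Distal peaks lay more than 2.5 kb from every TSS and were counted within 50 kb of a gene's TSSs. A promoter was CpG-rich when the 1000 bp centred on any TSS of the gene had an observed over expected CpG ratio of at least 0.6 and a GC fraction of at least 0.5. Genes with several TSSs had several chances to qualify for each of these measures.

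The analysis used 17 gene lists from textbook knowledge with 360 different genes, all fixed before the data were examined. Only Ets1 stood in 2 lists, and Ahsp had no match in the annotation. Each list's genes with a promoter peak were compared with all other protein-coding genes by a two-sided Fisher's exact test. Median promoter fold enrichment (0 for no peak), median domain width among genes with a domain and mean number of distal peaks were compared with 100000 random draws of as many genes in two-sided permutation tests. P-values were adjusted by the Benjamini-Hochberg method over the lists tested, and 0.05 was the threshold. Lists with fewer than 3 promoter domains were not tested for width. Genes are the units of these tests, are not independent replicates and can share promoters or domains, so a p-value describes these peak lists and not the spread between animals. Tests between pairs of lists, 5 pairs in all, were permutation or Fisher's exact tests added after the data were examined. Fisher's exact tests of peaks or genes and permutations ran in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3.

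Genes named in the text were chosen by a rule written before the data were examined. It took the 10 genes with the highest promoter fold enrichment and the 10 with the widest promoter domain. For each list it took up to 4 members each by fold enrichment, by width and, in alphabetical order, without a replicated promoter peak, plus members with a peak in 1 replicate's list only. It also took the 5 strongest distal peaks with their nearest protein-coding gene and the 5 genes with most distal peaks. Ties went by genome position.

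The overlap and list functions were tested on simulated data. With lists of 20 genes out of 21938, all planted lists with 3 or 19 members carrying a peak were called (100% of 200 each), as were lists with domains widened 3-fold (100%). Random lists were called in 4.5% of draws for promoter peaks and 4.0% for width. Lists drawn wholly from a simulated class of genes richer in peaks were called in 84% of draws by the unmatched Fisher's exact test. The exact test stratified by class called 3%, so each promoter call is given with both. The simulated class was assigned at random, not by CpG content, so these are not rates for CpG bias in the lists used here. Alternatives covered the overlap rule, a q-value below 0.01, the 20000 strongest peaks, promoter windows of 0.5 and 2.5 kb, joining gaps of 0 and 3 kb, distal windows of 100 kb, 1 TSS per gene, the pooled-read list, each replicate's own list in place of the replicated list, stricter CpG thresholds of 0.75 and 0.55, and backgrounds matched on CpG class or TSS density. Matching on CpG class used an exact test stratified by class for promoter peaks and stratified draws for width. Figures were drawn with matplotlib 3.10.9.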

Results

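H3K9ac was mapped in embryonic day 12.5 mouse midbrain, the part of the brain tube that later forms the tectum and tegmentum, in 2 pools of embryos. The replicate 1 list held 87089 peaks covering 41.7 Mb and the replicate 2 list held 60370 peaks covering 29.7 Mb. Calling on the reads of both replicates gave 83384 peaks, and the authors' replicated list held 32662 peaks covering 33.3 Mb with a median width of 744 bp. Read depth is unknown for both samples. Fold enrichment below is the value the authors gave each peak.

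The strongest peaks were mostly present in both replicates, and the weak ones mostly were not. Arid1a, a subunit of the SWI/SNF chromatin remodeller, carried the highest promoter fold enrichment of the replicated list, 46.8, at chromosome 4, 133749819 to 133757645, and its promoter peak reached 40.2 in the replicate 1 list and 37.7 in the replicate 2 list. Sox11, a transcription factor of newborn neurons, stood at 42.4 in the replicated list, 38.9 in replicate 1 and 33.9 in replicate 2. In contrast, Th, which encodes the tyrosine hydroxylase of dopaminergic neurons, had a promoter peak of 176 bp in replicate 2 and none in replicate 1. Sox10, a neural crest regulator, had a promoter domain of 1171 bp in replicate 1 and none in replicate 2. Of 21938 protein-coding genes, 14047 had a promoter peak in both replicates' own lists, 815 in replicate 1 only and 277 in replicate 2 only.

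Over all peaks, 30978 of the 87089 replicate 1 peaks overlapped a replicate 2 peak (35.6%), against 2.32% on average and 2.43% at most in 20 shuffles. In the other direction 35049 of 60370 replicate 2 peaks overlapped replicate 1 (58.1%, shuffled mean 3.34%). The shared sequence was 22.0 Mb of the 49.4 Mb covered by either list. Among replicate 1 peaks with a partner, fold enrichment correlated with that of the strongest overlapping replicate 2 peak (Spearman's rho 0.79, Pearson's r of log2 values 0.83, across 30978 peaks, which are not independent replicates). The correlation of promoter fold enrichment across the 14047 genes with a peak in both lists was 0.86 (Spearman's rho, across genes). The share of replicate 1 peaks with a partner was 91.1% in the strongest of 4 equal parts of the list and 11.3% in the weakest, and in replicate 2 it was 99.7% and 31.6%. When only the 20000 strongest peaks of each list were compared, the shares were 80.3% and 87.9%.

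**Figure D1:**
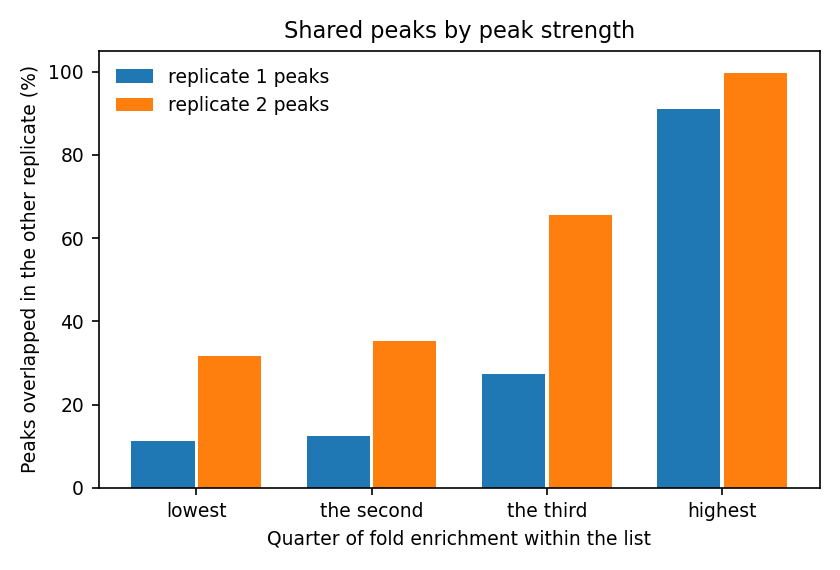
Share of peaks (%, vertical axis) overlapped by at least 1 base in the other replicate, for peaks ranked by fold enrichment within each list and divided into 4 equal parts (horizontal axis), replicate 1 in blue and replicate 2 in orange. The share rose from 11.3% to 91.1% in replicate 1 and from 31.6% to 99.7% in replicate 2.

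Every replicated peak had the coordinates of a pooled peak, and 39.2% of the 83384 pooled peaks were in the replicated list. The peaks kept were stronger and wider, with a median fold enrichment of 5.15 and a median width of 744 bp, against 2.73 and 216 bp for the 50722 left out. Of the kept peaks 62.0% lay at promoters, against 18.4% of those left out. Each of the 27603 pooled peaks that overlapped a peak of both replicates by 50% of either peak was in the replicated list. A further 5059 replicated peaks did not meet that overlap, 4135 of them covered in replicate 1 only, 809 in replicate 2 only and 115 in neither. Their median fold enrichment was 3.39, against 6.26 for the others.

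Most replicated H3K9ac peaks lay at promoters. Of the 32655 replicated peaks on main chromosomes, 20262 lay within 1 kb of a TSS (62.0%), 6.76 times the mean of 9.18% in shuffled positions, which ranged from 8.88% to 9.39%. Exons held a further 6.12%, introns 19% and the space between genes 12.7%, against shuffled means of 7.92%, 34.6% and 48.3%. Promoter peaks were also stronger and wider, with a median fold enrichment of 8.63 and a median width of 1081 bp, against 3.49 and 429 bp for intronic peaks. The promoter share depended on the list. It was 35.3% in replicate 1, 45.3% in replicate 2 and 35.5% in the pooled list, and in each it lay above the shuffled range. Introns held 35.5%, 29.8% and 35.6% of those lists, as much as promoters in the replicate 1 and pooled lists. Exons, below the shuffled mean in the replicated list, lay above it in those lists. They held 8.67% against 5.84% in replicate 1, 7.51% against 5.90% in replicate 2 and 9.12% against 6.10% in the pooled list. Promoters were assigned first, so their larger share leaves less for exons and introns. The exon share below the shuffled mean in the replicated list therefore does not show a deficit among peaks outside promoters.

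**Figure D2:**
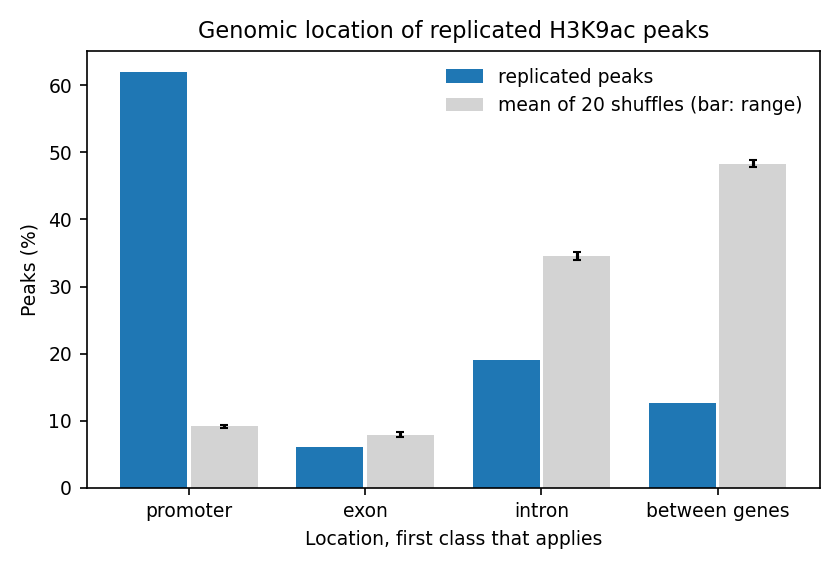
Share of replicated peaks (%, vertical axis) in promoters, exons, introns and between genes (horizontal axis; a peak counts in the first class that applies), in blue, beside the mean of 20 shuffles in grey with bars for their range. Promoters held 62.0% of peaks against a shuffled mean of 9.18%.

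In all, 14109 of 21938 protein-coding genes had a replicated promoter peak (64.3%). The 10 highest promoter enrichments belonged to Arid1a, Bicral (46.0), Actg1 (43.8), Sox11, Msi1 (42.0), Phc2 (41.7), Ywhaz (40), Skida1 (39.6), Bahcc1 (39.1) and Marcksl1 (38.8). Actg1 encodes a cytoplasmic actin, Msi1 an RNA-binding protein of neural stem cells, Phc2 a Polycomb protein and Ywhaz a 14-3-3 protein. Promoters with a peak were far more often CpG-rich. Of genes with a peak 77.7% were CpG-rich (10961 of 14109), against 3.63% of those without (284 of 7829), with an odds ratio of 92.5 (Fisher's exact test over genes, two-sided, p too small for double precision). Put the other way, 10961 of the 11245 CpG-rich genes and 3148 of the 10693 CpG-poor genes (29.4%) had a peak.

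Genes of midbrain patterning, neural progenitors and newborn neurons carried promoter peaks more often than other genes, and genes of blood, muscle, liver, germ cells, macrophages and the Hox clusters less often. All 25 neural progenitor genes had a replicated promoter peak (exact 95% interval 86.3% to 100%, Fisher's exact adjusted p = 6.64e-05), including Msi1, Sox2 (26.9) and Vim (25.2), which encodes the intermediate filament vimentin. Of 30 proneural and newborn neuron genes 29 had one (96.7%, exact adjusted p = 0.000148), with Sox11, Sox4 (33.3) and the proneural factor Ascl1 (25.4) at the top and Neurod4 without a peak. Of 30 midbrain and isthmus genes 27 had one (90%, exact adjusted p = 0.00346), led by Otx2 (28.5), which specifies forebrain and midbrain, and En2 (23.0), which patterns the midbrain and isthmus. Fgf17, Helt and Wnt1 were the exceptions. Helt and Wnt1 had promoter domains in both replicates' own lists, of 1173 bp and 3255 bp in replicate 1 and 327 bp and 788 bp in replicate 2, and Fgf17 had one of 338 bp in replicate 2 only. All 25 housekeeping genes had a peak (exact adjusted p = 6.64e-05), with Ywhaz and Actb (33.5) the strongest. These are two-sided Fisher's exact tests against all other protein-coding genes, adjusted over the 17 lists. With the exact test stratified by CpG class, the calls of midbrain and isthmus genes (adjusted p = 0.464) and housekeeping genes (0.338) were lost, and those of neural progenitor (0.0302) and proneural genes (0.00353) held.

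Both Hox lists were depleted. Of 23 anterior and central Hox genes 6 had a replicated promoter peak (26.1%, exact adjusted p = 0.000475), and of 16 posterior Hox genes only Hoxa13 had one (6.25%, adjusted p = 1.16e-05). Hoxa7 (5.15), Hoxa1 (4.95) and Hoxc6 (4.12) were the strongest, in domains of 306 bp, 527 bp and 435 bp. In replicate 1's own list 11 of the 23 anterior and central genes had a peak, and the call was lost (exact adjusted p = 0.0789), while 4 of 16 posterior genes had one and the call held (0.0012). With the exact test stratified by CpG class both calls held, with adjusted p-values of 4.86e-13 for the anterior and central list and 4.07e-18 for the posterior list. Neighbouring Hox genes lie in 4 clusters and are not independent.

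Of the lists of other tissues, germ cell genes had a peak in 2 of 20 cases (10%, exact adjusted p = 1.16e-05), liver in 3 of 22 (13.6%, 1.16e-05), microglia and macrophage in 2 of 18 (11.1%, 1.97e-05), cardiac and skeletal muscle in 5 of 22 (22.7%, 0.000305) and erythroid in 6 of 19 (31.6%, 0.00985). Alb, which encodes serum albumin, had a peak of 175 bp in replicate 2 only, and Hba-a1, an adult alpha globin gene that has a near-identical copy in Hba-a2, had none. Several peaks in these lists lay at promoters within 2 kb of a TSS of another protein-coding gene, namely those of Gdf9 (15.0), Foxa3 (18.2), Apoh (12.7), Trf (3.09), Mylpf (16.8) and Ckm (6.39). Without such genes the counts were 1 of 17 for germ cell, 0 of 19 for liver and 3 of 20 for muscle. The erythroid transcription factor genes Nfe2 (7.72), Klf1 (7.42) and Tal1 (5.15) and the macrophage factor gene Irf8 (5.83) had replicated peaks with no such neighbour. Stratifying the exact test by CpG class ended the calls of erythroid (adjusted p = 1.0), microglia and macrophage (0.0927), muscle (0.0927) and liver (0.116) genes, while that of germ cell genes held (1.27e-08). In the pooled list the microglia and macrophage call was lost (exact adjusted p = 0.0655, 8 of 18 genes), as was the muscle call (0.448). In replicate 1's own list the erythroid and muscle calls were lost (exact adjusted p = 0.127 and 0.451), with 13 of 22 muscle genes carrying a peak. The germ cell, liver and microglia calls held in both replicates' own lists, with counts of 6 and 3 of 20, 5 and 6 of 22, and 4 and 3 of 18 in replicates 1 and 2.

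The remaining lists did not pass the test against other genes. Dopaminergic neuron genes had a peak in 10 of 12 cases (exact adjusted p = 0.294), with Foxp1 (18.5) and Nr4a2 (17.2), a transcription factor gene required for dopaminergic neurons, the strongest, and Th and Aldh1a1 without one. Forebrain patterning genes had a peak in 20 of 24 cases (exact adjusted p = 0.0792), led by Lhx2 (15.0), while Eomes, Gsx2, Six6 and Tbr1 had none. Endothelial genes had 10 of 20 (exact adjusted p = 0.294), mesenchyme and pericyte genes 14 of 20 (0.691), neural crest and Schwann cell genes 11 of 14 (0.457) and late neuron, astrocyte and oligodendrocyte genes 12 of 20 (0.816). Lmo2 (14.6), Twist1 (8.30), Tfap2a (9.32) and Mbp (14.6) were among the strongest of these. The forebrain call depended on the replicate, since 24 of 24 genes had a peak in replicate 1's own list (exact adjusted p = 0.000382) and 19 of 24 in replicate 2's (0.26).

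**Figure D3:**
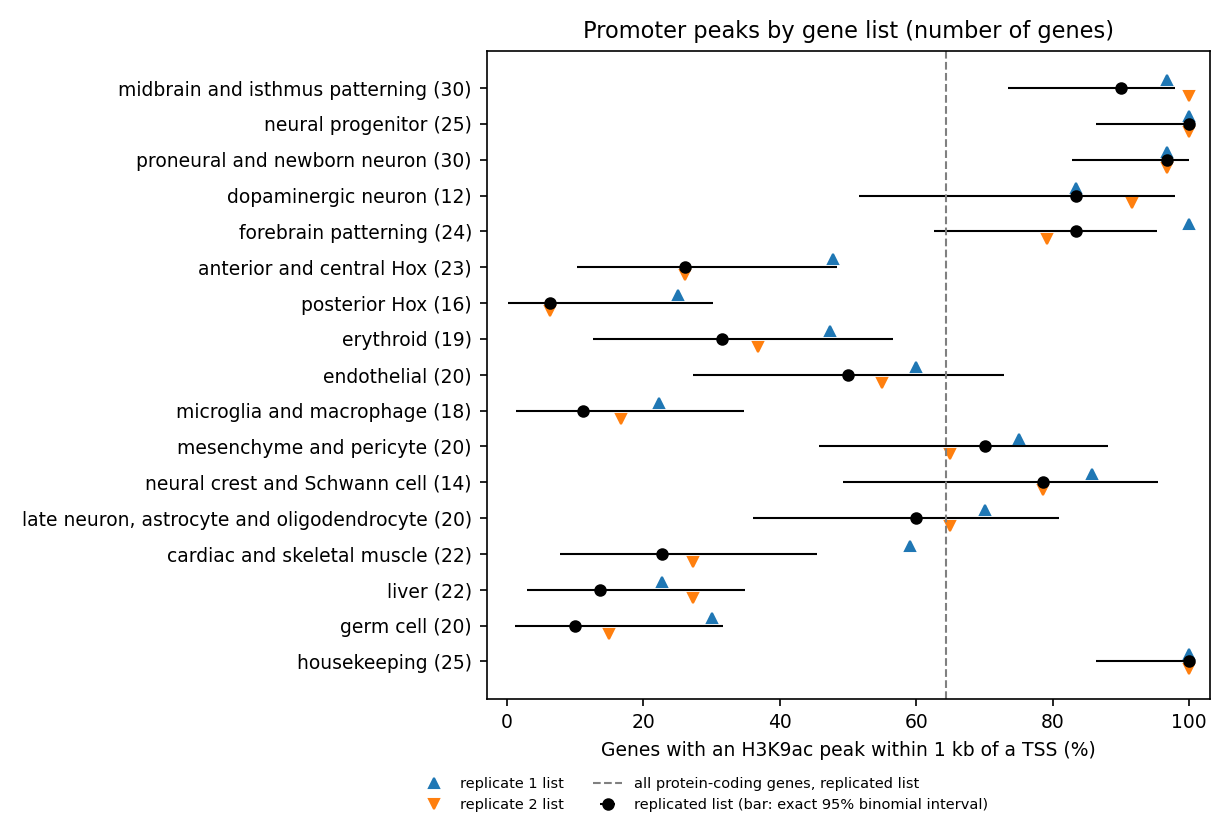
Share of genes (%, horizontal axis) with an H3K9ac peak within 1 kb of a TSS, by gene list (number of genes in parentheses). Black points with bars are the replicated list with exact 95% binomial intervals over genes, triangles are the replicates' own lists and the dashed line is the share of all protein-coding genes, 64.3%. The shares ran from 6.25% in posterior Hox genes to 100% in neural progenitor and housekeeping genes.

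By median promoter fold enrichment, with 0 for no peak, housekeeping (19.7) and neural progenitor genes (18) exceeded random lists of the same size, whose median was 7.55 (permutation tests, adjusted p = 0.00017 each, the smallest the draws could give). No other list passed, and proneural genes, at 12.8, lay above their random median of 7.56 (permutation adjusted p = 0.159). Both Hox lists and the erythroid, microglia, muscle, liver and germ cell lists had a median of 0, the lowest possible value. Random lists also reached 0 too often for this test to call them lower (permutation p = 0.108 to 0.195 before adjustment). Midbrain and isthmus genes had a median of 7.55, which did not pass the test (permutation adjusted p = 0.997). Their median lay below that of housekeeping genes (permutation test, adjusted p = 0.0006 over 5 pairs of lists) and above that of forebrain genes, 5.15 (0.0177). Proneural genes also lay below housekeeping genes (permutation adjusted p = 0.0391), and neural progenitor genes did not pass that test (0.428).

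The 10 widest promoter domains were at Nr2f2 (29.0 kb, chromosome 7, 70342832 to 70371859), Pou3f2 (23.0 kb), Pou3f3 (22.2 kb), Sox2 (21.1 kb), Otx2 (20.5 kb, chromosome 14, 48655027 to 48675519), Bahcc1 (20.2 kb), Meis2 (20.2 kb), Zfhx3 (19127 bp), Nr2f1 (18.5 kb) and Mn1 (18.4 kb). The Otx2 domain spanned the whole gene and was 20624 bp wide in replicate 1 and 19029 bp in replicate 2, whereas the Nr2f2 domain was 28794 bp wide in replicate 1 and 16709 bp in replicate 2, and the Nr2f1 domain 34954 bp and 15438 bp. Median domain width was 6327 bp in neural progenitor genes, 4972 bp in proneural and newborn neuron genes and 4741 bp in midbrain and isthmus genes, against medians of 1833 to 1836 bp in random lists (permutation tests, adjusted p = 9.33e-05 each, the smallest the draws could give). Housekeeping genes were intermediate at 2916 bp (permutation adjusted p = 0.00235). Each of the 3 developmental lists was wider than the housekeeping list in permutation tests, with adjusted p-values of 0.00072, 0.00368 and 0.00368, and midbrain genes were wider than forebrain genes (permutation adjusted p = 0.00368). The widest members were Pou3f2, Pou3f3, Sox2 and Pax6 (13.7 kb) among progenitor genes, Lhx5 (16.8 kb), Ebf3 (15.8 kb), Lhx1 (13.0 kb) and Dll1 (11.9 kb) among proneural genes, and Otx2, Meis2, Pax3 (17.3 kb) and Pax7 (16.9 kb) among midbrain genes.

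The 6 anterior and central Hox domains were narrow, with a median of 415.5 bp (permutation test, adjusted p = 0.00014), as were the 5 muscle domains at 678 bp (0.0193). Medians of the other tested lists did not pass the test. They were 1018 bp in erythroid, 1176 bp in endothelial, 1214 bp in mesenchyme and pericyte, 1302 bp in dopaminergic, 1482 bp in neural crest, 1755 bp in late neural and 1123 bp in liver genes. Posterior Hox, microglia and germ cell genes had too few domains to test. Forebrain patterning genes, with a median of 2021 bp in the replicated list (permutation adjusted p = 0.574), were called wide in replicate 1's own list at 3061.5 bp (permutation adjusted p = 0.00462) and narrow in replicate 2's at 813 bp (0.00539). They were also narrow without joining of peaks (971.5 bp) and among the 20000 strongest replicated peaks (1069 bp). Six3, an eye and forebrain regulator, had a domain of 16152 bp in replicate 1 and 6997 bp in replicate 2, and Emx1, a gene of the cerebral cortex, had 5048 bp and 927 bp. In single replicates' own lists erythroid domains were narrow, at 719 bp and 620 bp, as were liver domains in replicate 1 (242 bp) and endothelial domains in replicate 2 (616 bp). The muscle call was lost when permutation draws were matched on CpG class (adjusted p = 0.101), and the housekeeping call when peaks were not joined (0.297).

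**Figure D4:**
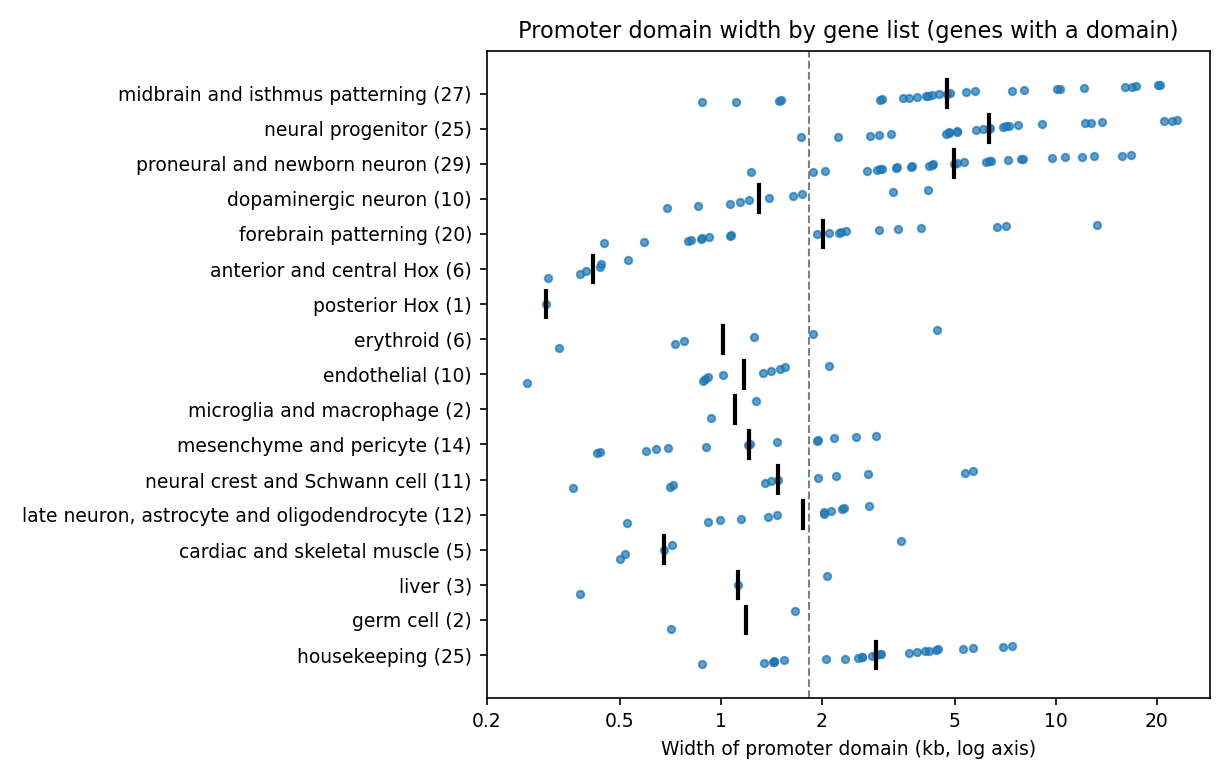
Width of the promoter domain (kb, log horizontal axis) of each gene with a domain in the replicated list, by gene list (number of such genes in parentheses); points are genes, black ticks are list medians and the dashed line is the median of all genes with a domain, 1834 bp. Neural progenitor, proneural and midbrain genes lie to the right with medians of 6327, 4972 and 4741 bp.

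**Figure D5:**
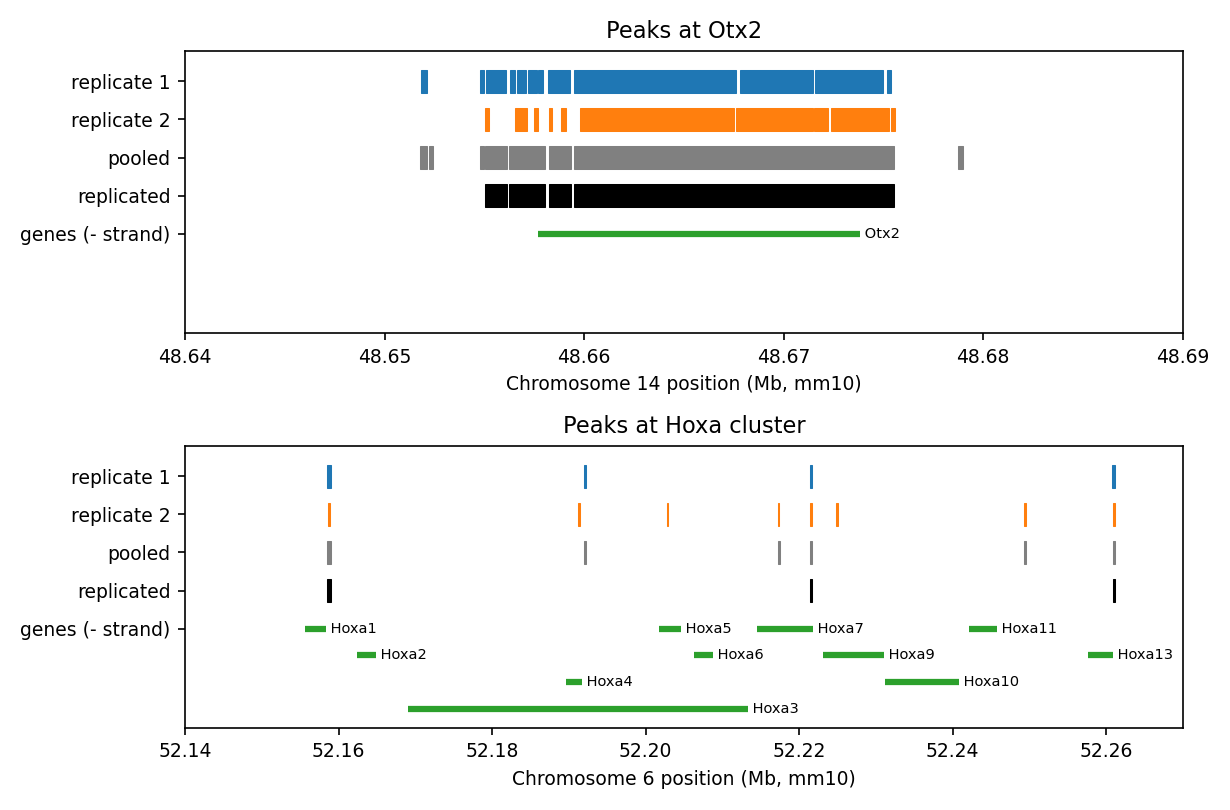
Peaks of the 4 lists (rows) along chromosome 14 at Otx2 and along chromosome 6 at the Hoxa cluster (horizontal axes, Mb on mm10), with the Otx2 and Hoxa genes in green, all on the minus strand. At Otx2 4 replicated peaks covered 20097 bp, and at the Hoxa cluster 3 replicated peaks covered 1134 bp.

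Distal peaks were more frequent near midbrain, neural progenitor and proneural genes than near random genes. The 9433 distal peaks were 28.9% of the replicated list and weaker than promoter peaks, with a median fold enrichment of 3.60. Of these, 48.6% overlapped introns and no exon, 12.6% exons and 38.9% neither. Midbrain and isthmus genes had 3.67 distal peaks within 50 kb on average, neural progenitor genes 3.48 and proneural genes 2.33, against means of 0.76 to 0.767 in random lists (permutation tests, adjusted p = 0.00034, the smallest the draws could give, 0.00051 and 0.00612). In the lists of replicates 1 and 2 the means were 10.5 and 7.1 for midbrain, 9.84 and 6.64 for progenitor and 6.57 and 4.63 for proneural genes, against 3.57 and 2.03 in random lists of the midbrain size, and the calls held. Peaks were counted without joining, so pieces of a wide promoter domain more than 2.5 kb from every TSS counted as distal. Midbrain, progenitor and proneural lists also had the widest domains, and counts without such pieces are not given. The highest counts in these lists, of genes named after their values were seen except En2, Pax7 and Ebf3, were 16 at Notch1, 14 at En2 and Msi2, 13 at Pax7 and 12 at Ebf3 and Nhlh1. Midbrain genes exceeded forebrain genes, which had 1.29 (permutation test, adjusted p = 0.0124 over 5 pairs of lists), and forebrain genes did not pass the test against random lists (permutation adjusted p = 0.41). Against housekeeping genes, midbrain genes passed the test (permutation adjusted p = 0.0297), and neural progenitor (0.0587) and proneural genes (0.304) did not. Anterior and central Hox genes had fewer, 0.0435 on average (permutation test, adjusted p = 0.00238), but among the 20000 strongest peaks the call was lost (0.149). These genes lie in clusters and share much of their 50 kb windows, so they are not independent. The test against posterior Hox genes (permutation adjusted p = 0.0426) rests on 1 distal peak each near Hoxb13 and the adjacent Hoxd9, Hoxd10, Hoxd11, Hoxd12 and Hoxd13, for which a single peak can be counted several times. The other 12 lists did not pass the test, with means of 1.56 in microglia, 1.52 in housekeeping, 1.43 in neural crest, 0.90 in endothelial, 0.75 in germ cell, 0.737 in erythroid, 0.727 in muscle, 0.65 in late neural, 0.636 in liver, 0.60 in mesenchyme, 0.417 in dopaminergic and 0.375 in posterior Hox genes. In replicate 1's own list posterior Hox genes were called lower (1.19 on average, permutation adjusted p = 0.0304). Gse1 had the most distal peaks nearby, 46, followed by Ephb2 (23), Zmiz1 (23), Bahcc1 (22) and Igdcc3 (20). The windows of all TSSs of a gene counted together, so genes with spread TSSs had more sequence searched.

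The 5 strongest distal peaks all lay between genes and overlapped peaks in both replicates. The first, with a fold enrichment of 20.0, was at chromosome 11, 119056231 to 119057587, 15.3 kb from the nearest protein-coding TSS, that of the Polycomb gene Cbx8. The others were at chromosome 1, 86487670 to 86488919 (19.4, 37.8 kb from Ptma) and 86440701 to 86443729 (19.2, 14.4 kb from Tex44), chromosome 4, 34886131 to 34887396 (19, 3.17 kb from Zfp292) and chromosome 7, 73616530 to 73618418 (18.5, 74.7 kb from Chd2). Distal peaks were less often found in both replicates' own lists than promoter peaks, 71.9% against 92.2% at an overlap of 50% of either peak. Replicate 1's own list held 94.5% of the distal peaks and replicate 2's 76.7%. The comparison was not matched on strength, and the median fold enrichment was 3.60 at distal and 8.63 at promoter peaks.

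The X chromosome held fewer replicated peaks per Mb, 4.27, than any autosome, which ranged from 8.26 on chromosome 14 to 24.3 on chromosome 11. Relative to the autosomes together (13.0 per Mb) the X stood at 0.33, and at 0.205 and 0.236 in the lists of replicates 1 and 2. The share of protein-coding genes with a promoter peak was 46.3% of 948 on the X and 65.7% of 20807 on autosomes. The Y chromosome held 2 replicated peaks.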

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

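Unplaced or unlocalized scaffolds held 7 replicated peaks, which entered the totals and overlaps of the lists but no location or gene result. The strongest had a fold enrichment of 10.8, on a scaffold assigned to chromosome 4. Depth is unknown, and no control samples were analysed here.

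In the next 2 patterns, the forebrain tests by rank of fold enrichment and of width among genes with a peak in both replicates were chosen only after the result was seen.

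Most replicate 1 peaks had no replicate 2 partner. GC-rich sequence taken up by replicate 1 alone stays open. In the weakest of 4 equal parts of the list unshared peaks had a median GC of 50.6%, below the 52.9% of shared ones. Both medians lay above the highest value in shuffled positions, 42.0%. The lower GC of unshared peaks met the bound set in advance against uptake of GC-rich sequence. Even so, the contrast of shared with unshared peaks cannot decide, since 31.4% of the shared and 15.8% of the unshared lay at promoters. Replicate 1 peaks had a median GC of 55.2% at promoters and 50.7% in introns. Weak calls near the peak threshold may account for much of the pattern, because 11.3% of the weakest part was shared. The strongest part reached 91.1%, short of the bound set in advance, so this explanation stays open, with 1945 unshared peaks there. Depth, which could set how many weak peaks are called, is unknown and was not tested, and no biological explanation was tested, as the pools belong to 1 group.

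Forebrain patterning genes had wide promoter domains in replicate 1 and narrow ones in replicate 2. A general narrowing in replicate 2 was argued against by the 19 genes with a peak in both. Their median log2 width ratio was 1.21 against 0.397 in matched random lists (permutation adjusted p = 0.0156). Of the list's 24 genes, all with a replicate 1 peak, only 23 entered a second ratio. With the 4 of these lacking a replicate 2 domain set to a width of 175 bp there, this ratio was 1.95 against 0.43. It lay at percentile 100 (permutation adjusted p = 0.00028 over 14 lists, the smallest the draws could give). By that ratio endothelial (1.12) and neural crest genes (1.06) lay on the same side without passing the test (permutation adjusted p = 0.107 each). More forebrain tissue in the pool of replicate 1 is a candidate explanation that stays open, because the bounds set for it in advance, met with 18 genes above the median of their match class, restate the pattern and lend it no support. These bounds were written for 24 genes, and 23 were tested. By rank of fold enrichment in replicate 1 over replicate 2 the list lay at percentile 28.4 among genes with a peak in both and, with the 4 others placed last in replicate 2, at 99.3, and passed neither test (permutation adjusted p = 0.92 and 0.207). Splitting of weak regions also stays open, since without joining of peaks the forebrain median of the replicated list was 971.5 bp, and no difference between the pools' dissections was tested.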

How the results depend on the processing

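The tests with replicated peaks called in both replicates, with genes without a neighbouring TSS and with microglia genes other than C1qa, C1qb and C1qc were chosen after the data were examined, as were, for width, the 20000 strongest peaks, other promoter windows and 1 TSS per gene and, for distal peaks, the 20000 strongest and 1 TSS per gene. Of 535 alternative values of the 48 list results, 467 kept their direction and side of the threshold, 14 lost a call, 21 gained a call and 33 changed direction. Of these 33, 3 passed the threshold, all for forebrain width, and 30 were past it in neither setting. The 48 results cover promoter peaks, width and distal peaks, and alternatives for median promoter fold enrichment are not among them. The count of genes with a promoter peak stayed within 1.5 times of 14109 under each alternative, and the CpG contrast stayed past its threshold. Domain widths of the 176 named genes moved by no more than the spread between replicates in 1429 of 1760 alternatives. Depth is unknown and limits how weak calls can be read. Causes of the changes below were not tested.

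The share of replicate 1 peaks overlapping replicate 2 was 31.9% when 50% of either peak had to be covered, 23.6% at reciprocal 50%, 43.2% at q below 0.01 and 80.3% among the 20000 strongest. The share of replicate 2 peaks was 52.9%, 34.1%, 68.6% and 87.9%. The rank correlation was 0.80 at q below 0.01, 0.893 at reciprocal 50% and 0.818 for −log10 p. The share of pooled peaks in the replicated list was 51.1% at q below 0.01. The promoter share was 35.5% in the pooled list, 82.2% among the 20000 strongest peaks and 71.1% in the 2.5 kb window, and 35.3% to 45.3% in the lists of single replicates, in which X over autosomes was 0.205 to 0.236.

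For promoter peaks, CpG matching left 2 lists called higher (from 4) and 3 lower (from 7). It ended the calls of midbrain (90.0%), housekeeping (100%, where the matched test could not make a call), erythroid (31.6%), microglia (11.1%), muscle (22.7%) and liver genes (13.6%). The pooled list ended those of microglia (44.4%) and muscle (59.1%) and added forebrain (95.8%), as did the genes without a neighbouring TSS (87.0%). Endothelial genes became depleted among the 20000 strongest peaks (35.0%) and with 1 TSS per gene (30.0%). In single replicates' lists 4 to 7 lists were called lower, and shares ran from 79.2% to 100% in forebrain, 26.1% to 47.8% in anterior Hox, 36.8% to 47.4% in erythroid and 27.3% to 59.1% in muscle genes. Without a call in either setting, late neural genes turned from the lower to the higher side in the 2.5 kb window and the pooled list (70% each), under CpG matching and without a neighbouring TSS (60% each), and without replicate 2 (single replicates 65% to 70%). Mesenchyme turned to the lower side among the 20000 strongest peaks (45%) and without replicate 1 (single replicates 65% to 75%), and forebrain under CpG matching (83.3%).

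For width, no joining gave 4 lists called narrow (from 2), the pooled list 5, CpG matching 1 and each single replicate's list 6. Without joining, the forebrain median turned to the narrow side (971.5 bp), mesenchyme became narrow (855 bp) and housekeeping lost its call (1728 bp). Forebrain genes became wide with a 3 kb gap (3836 bp) and in the pooled list (3375 bp), where erythroid (753 bp) and liver (324 bp) became narrow. CpG matching ended the muscle call (678 bp), and endothelial genes became narrow among peaks called in both replicates (966.5 bp) and with 1 TSS per gene (908.5 bp). Erythroid genes became narrow in the 0.5 kb window (775 bp), and forebrain genes turned narrow among the 20000 strongest peaks (1069 bp). Single replicates' lists gave 813 to 3061.5 bp in forebrain, which turned to the narrow side without replicate 1, 620 to 719 bp in erythroid, 616 to 1386 bp in endothelial and 242 to 1008.5 bp in liver genes. Without a call in either setting, crest genes turned to the wide side with no joining (1482 bp) and a 3 kb gap (2201 bp). Late neural genes did so with a 3 kb gap (2033 bp), in the pooled list (2220.5 bp), under CpG matching and without a neighbouring TSS (1754.5 bp each) and without replicate 2 (single replicates 1407 to 2017.5 bp).

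For distal peaks, microglia genes were called within 100 kb (3.94 on average), and posterior Hox genes in the pooled list (1.13), which raised the lists called lower to 2. In single replicates' lists that count was 1 to 2, and the posterior Hox mean 1.19 to 1.81. Among the 20000 strongest peaks no list was called lower (0), and anterior Hox lost its call (mean 0). Without a call in either setting, direction turned among these peaks for mesenchyme, late neural (0.30 each) and liver genes (0.273), and in the pooled list for dopaminergic (4.67), endothelial (3.15), late neural (4.55) and muscle genes (3.82). It also turned for muscle within 100 kb (1.68) and with 1 TSS per gene (0.682), and for endothelial genes without a neighbouring TSS (0.588). Without replicate 2 it turned for dopaminergic (single replicates 2.0 to 4.33), endothelial (2.2 to 3.35) and late neural genes (1.95 to 4.55), and without either replicate for muscle genes (2.09 to 4.45). The microglia call within 100 kb rested on C1qa, C1qb and C1qc, which lie together near Ephb2. Without them the mean of 15 genes was 1.33 (permutation test, p = 0.927).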

Other observations

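In the list of late neuron, astrocyte and oligodendrocyte genes 12 of 20 had a replicated promoter peak (60%), against 64.3% of all protein-coding genes (Fisher's exact test, adjusted p = 0.816). Of these, Mbp (14.6), Gabra1 (11.5), Bdnf (11.3) and Syt1 (10.8) had replicated promoter peaks with domains of 2032, 2298, 2325 and 2034 bp. Mbp encodes myelin basic protein, Gabra1 a GABA receptor subunit, Bdnf a neurotrophin and Syt1 a synaptic vesicle protein. The astrocyte genes Gfap, Aldh1l1 and Aqp4 each had a promoter peak of 170 to 217 bp in 1 replicate's list only, and Mag had none. A promoter peak was measured over any annotated TSS, including those of longer transcripts of a gene. That of Mbp lay at chromosome 18, 82474806 to 82476837, at the outer start of an annotated gene that runs to 82585637. Which Mbp transcripts start there was not examined, so the peak cannot be assigned to the transcripts of myelin.

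Of the crest list, Mpz, which encodes a myelin protein of Schwann cells, had the highest enrichment (14.4), at a promoter within 2 kb of a TSS of another protein-coding gene. Tfap2a (9.32) and Tfap2b (7.04) had domains of 5644 and 5365 bp in the replicated list, and that of Tfap2b was 5176 bp in replicate 1 and 1157 bp in replicate 2. Among mesenchyme genes Twist1 (8.30), Foxd1 (8.13), Prrx1 (7.55) and Foxc1 (6.18) had replicated peaks, while the collagen gene Col3a1 and the smooth muscle actin gene Acta2 had none in any replicate.

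The 5 genes with the most distal peaks nearby had 134 such peaks between them, with a median fold enrichment of 3.69 against 3.60 for other distal peaks. Pieces of broad domains cut into several peaks could raise the count, and joining peaks 1 kb or less apart left 61.2% of it (82 of 134), between the bounds set in advance, so the explanation stays open. GC-rich sequence also stays open, since the median GC of these peaks was 56.1%, above the median of 53.6% of other distal peaks and below the bound set in advance (57.1%). Bounds of both tests were set before their results were seen. No biological explanation was tested. Nor was the length of sequence searched, which grows with the spread of a gene's TSSs.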
